A study of Homo sapiens with 4 samples.

How the data were processed

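Visium HD, a slide assay that captures RNA on a grid of barcoded squares, was run on formalin-fixed kidney biopsy cores of 4 people with type 2 diabetes before treatment with an SGLT2 inhibitor. The biopsies form 1 group and are called replicates 1, 5, 7 and 9, the numbers in their labels. Each person gave 1 sample, so people were described and not tested against each other, and no sample taken after treatment was used here. The deposited matrices hold raw UMI counts (distinct captured molecules) per gene and 8 um bin, which the authors made with Space Ranger 3.1.1 on GRCh38, per the file headers and the labels. Seurat 5 is also named in the submitters' processing notes, and its role, the aligner and any filter on bins are not given in the sources used here. The deposited bin names gave each bin's row and column on the array, and the deposited feature tables paired Ensembl gene IDs with symbols for 37082 features. The deposited image scale factors were not used here.

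The deposited counts of 3 by 3 neighbouring bins were added into squares of 24 um. Squares with fewer than 5 bins or 100 UMIs were left out. Counts were scaled to the square's total and log transformed, and the 2000 most variable genes were taken, without mitochondrial genes or any symbol of the tested lists. A second deposited feature of CCL2, carried under a deprecated ID, was not caught by this rule and took part in clustering, as did one of SLC2A3 with 16 um and 32 um squares. XIST and Y-linked genes (90 features) were not taken out of the clustering, but were left out of the leading genes, every sum and every test. Each gene was centred within its biopsy, 30 principal components were computed, and squares were clustered over the 4 biopsies with the Leiden algorithm at resolution 1 on a graph of 15 neighbours. A cluster took the name of a region when the median log2 fold of that region's markers, fixed before the data were examined, over all other squares was at least 1, with at least 3 markers detected and no other region's markers in greater number among its 10 leading genes. Clusters with a median under 200 UMIs were set aside as low in UMIs, a threshold set after the data were seen. One cluster passed no marker list and had HAVCR1 among its 50 leading genes. It is called the HAVCR1-led region, and its comparison was added after the regions were seen.

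Raw UMIs were then added up per biopsy and region, giving 36 sums, and the biopsy was the unit of replication. Genes were kept with filterByExpr (minimum count 10) and sums were scaled by TMM. edgeR 4.0.16 quasi-likelihood tests with the biopsy as a block gave log2 fold changes, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The 36 sums were fitted together, so all regions shared an estimate of the spread. Each SE given with a fold is the absolute log2 fold change over the square root of the F statistic. It is not the spread of the paired differences, and n is the number of biopsies. The block is justified because the sums of a number come from the same biopsy. A further 3 comparisons used 8 sums each. Proximal and thick limb squares were called near when at least 1 of 8 neighbouring squares was interstitial and far when none within 2 squares was. Proximal squares were also divided by whether they held a UMI of 12 tubular injury class genes after thinning each square to 100 UMIs, and those genes were left out of that test.

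Gene lists were written from textbook knowledge before the data were examined. They were HIF machinery, HIF targets (glycolysis, other, and both joined), gluconeogenesis, glucose transport, fatty acid oxidation, oxidative phosphorylation, sodium transport, tubular injury class genes, other tubular injury genes, matrix and fibrosis, inflammation, and early response and heat shock. They were compared with all other tested genes by camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists. Each list was also tested with an estimated correlation. LDHA, PGK1, GAPDH, ALDOA, TPI1, PFKL, PDK1, CA9, BNIP3, TF, CLDN16, SLC14A2, SDHD, UQCRFS1, COX5A, ATP5F1A, ICAM1, IL6, IL1B and HSPA1B each had fewer than 20 UMIs over all biopsies and were not measured here. G6PC1 and NHERF1 are named G6PC and SLC9A3R1, as in the deposited tables.

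Genes named in the text followed a rule set before the data were examined. HIF1A, EPAS1, HIF3A, VHL, EGLN1, EGLN3, VEGFA, SLC2A1, LDHA and SLC5A2 were always included where tested. To these were added the 2 largest rises and 2 largest falls of each list that passed the threshold in the same direction in all 4 biopsies, and the 5 largest rises and 5 largest falls over genes that are no region markers with a mean log2 CPM of at least 5. Gene positions came from the reference annotation of GRCh38, matched on symbols for 128 of 133 named genes.

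The tests were tried on simulated counts drawn gene by gene from real means and library sizes. Both classes compared were given the same means, except for 100 genes changed 2-fold, 100 changed 4-fold and the HIF targets shifted by 0.5. The 4 region comparisons over 11286 genes recovered 61%, 48%, 65% and 53% of the 2-fold changes for thick limb, glomerulus, interstitium and HAVCR1-led squares, and 92%, 86%, 94% and 90% of the 4-fold changes. The proximal near and far comparison recovered 69% and 94% over 8427 genes, the thick limb one 63% and 97% over 1915 genes, and the injury comparison 32% and 79% over 8025 genes.

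Alternatives were the fit without the block, each biopsy left out in turn, RLE factors, no filter on low counts, squares of 16 um and 32 um clustered anew, a minimum of 200 UMIs per square, clustering at resolution 0.5, regions from marker UMIs instead of clusters (at least 3 UMIs), DESeq2 1.42.0, a fit on the 2 regions alone, near defined by at least 3 neighbours, the injury class defined by at least 2 UMIs, and an estimated correlation. Python 3.11.15, scipy 1.17.1, leidenalg 0.10.2 and R 4.3.3 were used.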

Results

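Kidney biopsy cores of 4 people with type 2 diabetes, taken before treatment with an SGLT2 inhibitor (a drug that blocks glucose uptake in the proximal tubule), were measured with a spatial RNA assay. The 4 biopsies held 154937, 215426, 175742 and 342526 bins of 8 um in replicates 1, 5, 7 and 9, with 4623119, 4652474, 5047538 and 8632389 UMIs. After bins were joined, 5946, 7287, 5888 and 11520 squares of 24 um were kept, holding 94.8%, 91.7%, 92.2% and 90.8% of the UMIs. The median square held 602, 455, 504 and 535 UMIs, and 17039, 17324, 17312 and 17814 genes were detected. Mitochondrial transcripts made up 6.76%, 3.34%, 4.07% and 5.31% of the UMIs in kept squares. GPX3, a secreted peroxidase made by the proximal tubule, had the most UMIs in every biopsy but replicate 7, where the immunoglobulin light chain IGKC did. All biopsies belonged to 1 group, so every comparison was made between regions or classes of squares within each biopsy.

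Squares fell into 9 regions, 8 of them named by fixed marker lists. The proximal region covered 38.1% ± 7.35 (SD, n = 4) of the squares in named regions, and the interstitium, led by fibroblast and immune transcripts, 20.7% ± 10.999. Shares were 7.38% for the intercalated, 6.62% for the thick limb, 6.54% for the glomerular, 6.499% for the distal, 5.14% for the vascular and 3.21% for the principal cell region. A further region, with HAVCR1 (the injury marker KIM-1) among its leading genes and no segment's markers, covered 5.79% ± 3.68, from 1.04% to 9.25%. Shares depended on how regions were drawn: with regions from marker UMIs they were 59.9% for the proximal, 0.979% for the intercalated, 4.29% for the glomerular and 3.27% for the vascular region. The intercalated share was 2.999% and the thick limb share 4.41% with 16 um squares, the interstitial share 12.8% with 32 um squares, and the principal cell share 5.47% and 5.73% with 16 um and 32 um squares. HAVCR1-led squares numbered 225, 546, 342 and 82 in replicates 1, 5, 7 and 9. Clusters with few UMIs, set aside by a threshold chosen after the data were seen, held 21.5%, 19.0%, 27.8% and 31.4% of the squares. Among them, a cluster of 1638 squares met the marker rule for principal cells (median log2 fold 1.84), against 728 squares in the named principal cell cluster. Another, of 673 squares, met the rule for the glomerulus (2.59), against 1507 in the named cluster. The principal cell and glomerular shares above leave these squares out.

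**Figure D1:**
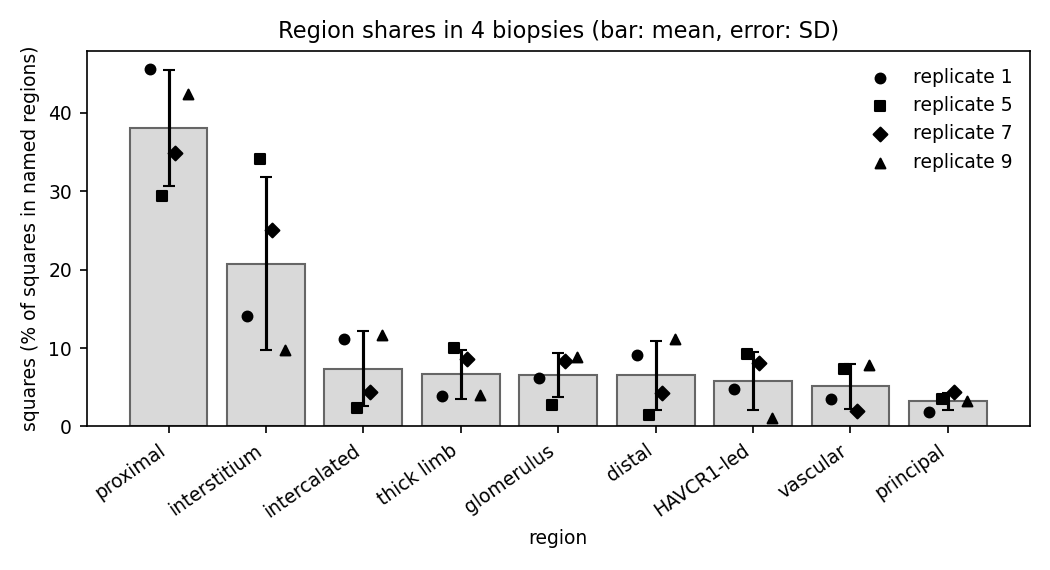
Percent of squares in named regions (vertical axis) for 9 regions (horizontal axis) in 4 biopsies; bars are means, error bars SD and symbols single biopsies. The proximal region had the highest mean, 38.1%, and the HAVCR1-led region ranged from 1.04% to 9.25%.

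Proximal squares of different biopsies came largely from different clusters. Replicates 1 and 9 gave 1950 and 2771 squares to a cluster led by SLC36A2, PRODH2 and SLC34A3, against 313 and 329 from replicates 5 and 7. A cluster led by AGT, SLC22A12 and SLC5A8 held 1314 and 1031 squares of replicates 5 and 7, against 0 and 1 of replicates 1 and 9. The third, led by SLC7A13, GC and AGXT, held 181, 106, 123 and 578 squares of replicates 1, 5, 7 and 9. These genes led the clusters and are no findings. Mitochondrial transcripts made up 7.92% ± 1.16 of the UMIs in the proximal region, 4.74% ± 2.36 in the thick limb, 3.51% ± 1.96 in the interstitium, 3.18% ± 0.86 in HAVCR1-led squares and 1.83% ± 0.09 in the glomerular region (SD, n = 4). Transcripts of a region also appeared next to it: UMOD, made by the thick limb, reached 10.8% ± 3.82 of its thick limb level in proximal squares that touched the thick limb, 2.34% at a distance of 2 squares and 0.256% at 5 or more.

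The series title names the hypoxia-inducible factor (HIF) network, so transcripts of the HIF system were compared across regions. EPAS1, which encodes HIF-2 alpha (ENSG00000116016, chromosome 2, 46297407 to 46386697 on GRCh38), and HIF1A, which encodes HIF-1 alpha (ENSG00000100644, chromosome 14, 61695513 to 61748258), were both measured. In the proximal region EPAS1 stood at 583 ± 136 CPM (counts scaled to the library total) and HIF1A at 34.2 ± 13.9 (SD, n = 4). In the glomerular region they stood at 3528 ± 545 and 61.7 ± 29.5. GAPDH, ALDOA, TPI1, PGK1 and LDHA had 0 UMIs in this assay, for a reason that was not tested. Counts may thus not be comparable between genes, so levels of different genes are not ranked here.

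**Figure D2:**
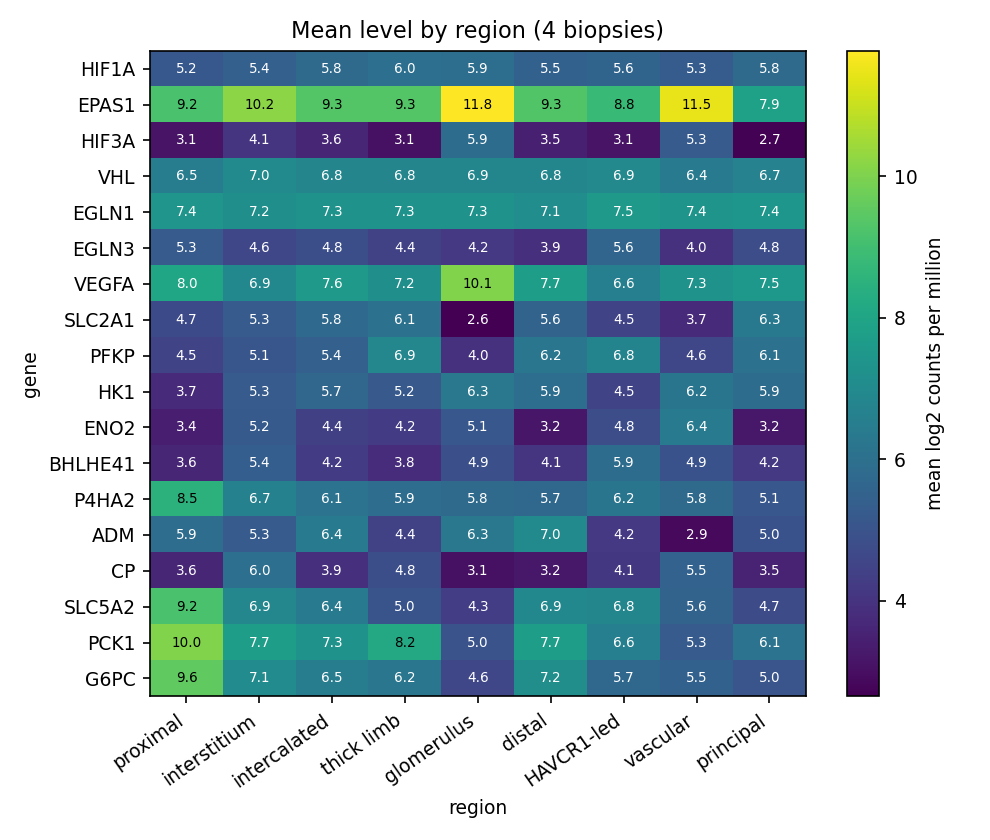
Mean level in log2 CPM (colour and printed values) of 18 HIF and glucose genes (vertical axis) in 9 regions (horizontal axis), averaged over 4 biopsies. EPAS1 and VEGFA were highest in the glomerular region, and SLC5A2, PCK1 and G6PC in the proximal region.

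The first comparison asked how the thick ascending limb, which reabsorbs salt, differed from the proximal tubule. Glycolytic HIF targets were higher in the thick limb: PFKP, a phosphofructokinase, by 2.46 ± 0.29 on the log2 scale (SE, n = 4; adjusted p = 1.5e-09), SLC16A3, a lactate exporter, by 1.84 ± 0.39 and SLC2A1, the glucose transporter GLUT1, by 1.499 ± 0.26, each in 4 of 4 biopsies. SLC16A3 no longer passed without replicate 7 (1.29, adjusted p = 0.0562), and PFKP stood at 1.47 with regions from marker UMIs. HIF1A was higher by 0.82 ± 0.28 (adjusted p = 0.0194), a difference that no longer passed without replicate 7 (0.47, adjusted p = 0.327) or 9 (0.73, adjusted p = 0.0544), with 16 um or 32 um squares (0.50 and 0.58) or with regions from marker UMIs (0.46), while EPAS1 did not differ detectably (0.15 ± 0.21). SLC5A2, which encodes SGLT2 (ENSG00000140675, chromosome 16, 31483123 to 31490769), fell by 4.22 ± 0.38. The glucose producers PCK2 and G6PC fell by 3.04 ± 0.25 and 3.35 ± 0.28, VEGFA by 0.85 ± 0.20 and the collagen hydroxylase P4HA2 by 2.73 ± 0.22. The VEGFA call was lost with regions from marker UMIs (-0.36, adjusted p = 0.203) and without the biopsy block (-0.83, adjusted p = 0.0591). SCNN1A, a subunit of the epithelial sodium channel, was higher by 3.29 ± 0.23 and the kinase STK39 by 2.48 ± 0.27. Markers of other cell types were also higher in these squares: 5 of 7 principal cell markers (median 1.32), 3 of 9 intercalated cell markers (0.98) and 9 of 17 immune markers (1.35).

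Across the thick limb comparison, 1969 genes were higher and 1946 lower of 11286 tested. The median of the glycolytic HIF targets was 1.47 above the proximal level (8 higher and 1 lower of 11; camera adjusted p = 0.00835). Within single biopsies the median of this list was 0.54, 0.85, 1.58 and 0.84 in replicates 1, 5, 7 and 9. Glucose transport genes had a median of -2.94 (0 higher, 4 lower of 4; adjusted p = 5.25e-05) and fatty acid oxidation genes -1.28 (adjusted p = 3.81e-07). Gluconeogenesis genes had a median of -2.45 (adjusted p = 0.00185; adjusted p = 0.122 with an estimated correlation), sodium transport genes 0.997 (adjusted p = 0.0396; adjusted p = 0.339 with an estimated correlation) and other tubular injury genes 0.59 (adjusted p = 0.00476; adjusted p = 0.236 with an estimated correlation). The sodium transport call was also lost without replicate 1 (0.72, adjusted p = 0.0524), without replicate 9 (0.93, adjusted p = 0.064), with 32 um squares (0.90, adjusted p = 0.0757) and in a fit on the 2 regions alone (1.03, adjusted p = 0.0715). The other tubular injury list turned to -0.02 with 16 um squares and -0.06 with regions from marker UMIs. Proximal tubule markers had a median of -3.32 (20 of 20 lower). The lower glucose transport, gluconeogenesis and fatty acid oxidation lists were not tested apart from this general fall of proximal genes. All HIF targets together were not separated (median 0.17 and mean 0.09, test direction down, adjusted p = 0.983), with 14 higher and 11 lower of 40, or 15 and 11 adjusted over the list alone. Their median turned to -0.04 without replicate 7 and to -0.13 with no filter on low counts. Oxidative phosphorylation genes did not differ as a list (median -0.02, adjusted p = 0.431), nor did HIF machinery (0.07, adjusted p = 0.714). The largest rises were SIM2 (5.72), GP2 (5.57), TMEM207 (5.43), ACPP (5.24) and PAPPA2 (5.21), and the largest falls APOC3 (-5.56), STRA6 (-5.41), CALML3 (-4.58) and PRODH2 (-4.30). ACPP, GP2, PAPPA2, PRODH2 and TMEM207 had taken part in clustering, and SIM2, APOC3, STRA6 and CALML3 led a thick limb or proximal cluster, so these values describe how the regions were drawn. Among genes that had not, 1509 were higher and 1793 lower of 9713.

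The glomerulus, the filtering unit, was compared with the proximal tubule next. HIF machinery was higher there: HIF3A by 3.33 ± 0.43 on the log2 scale and EPAS1 by 2.61 ± 0.22 (SE, n = 4; adjusted p = 9.29e-09 and 5.8e-14), each in 4 of 4 biopsies. Endothelial markers (6 of 9 higher, median 2.81) and vascular smooth muscle markers (6 of 8, median 1.73) were higher in the same squares. VEGFA, the vascular growth factor made by podocytes (ENSG00000112715, chromosome 6, 43770211 to 43786487), was higher by 2.06 ± 0.18, the lipase inhibitor ANGPTL4 by 4.90 ± 0.67 and hexokinase HK1 by 2.86 ± 0.32. Other HIF targets were lower, with SLC2A1 at -2.06 ± 0.51, EGLN3 at -1.71 ± 0.44, HMOX1 at -3.20 ± 0.29 and AK4 at -3.74 ± 0.34. The EGLN3 difference did not pass without replicate 9 (-0.98, adjusted p = 0.145), where SLC2A1 stood at -3.64, and HK1 stood at 1.90 with regions from marker UMIs. HIF1A did not pass the test (0.67 ± 0.32, adjusted p = 0.074), but did with clustering at resolution 0.5 (0.73, adjusted p = 0.0475) and in a fit on the 2 regions alone (0.76, adjusted p = 0.0167). SLC5A2 fell (-4.33 ± 0.41), as did PCK1 (-5.09 ± 0.41) and SLC9A3, a sodium and proton exchanger (-4.24 ± 0.35). The matrix genes POSTN and CCN2 were higher by 7.03 ± 0.31 and 4.23 ± 0.22. HAVCR1 had 0 UMIs in glomerular squares and 41 in proximal squares, which made it at least 2.79-fold lower against a floor of 3 counts over the class.

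In the glomerular comparison 2919 genes were higher and 2872 lower of 11286. HIF machinery had a median of 0.81 (4 higher, 0 lower of 8; adjusted p = 0.011), and HIF targets a median of -0.03 and a mean of 0.00 (adjusted p = 0.722; 12 higher and 15 lower of 40, the same counts adjusted over the list alone), and the median was -0.20 without replicate 1 and -0.24 with regions from marker UMIs. Fatty acid oxidation had a median of -2.18 (adjusted p = 2.25e-10), oxidative phosphorylation -1.14 (0 higher, 35 lower of 35; adjusted p = 1.28e-09), gluconeogenesis -3.95 (adjusted p = 7.98e-06) and glucose transport -4.20 (adjusted p = 0.000711). Matrix and fibrosis genes had a median of 1.73 (14 higher, 0 lower of 17; adjusted p = 5.62e-07). Of 9 fibroblast markers 5 were higher and 2 lower (median 0.56), and 3 of 3 red blood cell markers were higher (2.69). Proximal tubule markers had a median of -4.40 (20 of 20 lower), and the lower metabolic lists were not tested apart from this general fall of proximal genes. Sodium transport genes had a median of -1.66 (adjusted p = 0.00983; adjusted p = 0.195 with an estimated correlation). The tubular injury class genes had a median of 0.54 (adjusted p = 0.6), which was the same with HAVCR1 at its bound. IL1RL1 (8.48), PTPRQ (7.80), NDNF (7.63), PCOLCE2 (7.42) and DDN (7.41) were the largest rises and had all taken part in clustering, most as leading genes of the glomerular cluster, and STRA6 (-6.07), MT1H (-5.81), PNPLA3 (-5.80), CYP17A1 (-5.41) and VIL1 (-5.41) the largest falls, of which MT1H had taken part in clustering and STRA6 led a proximal cluster. Among genes that had not, 2208 were higher and 2651 lower of 9713.

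The interstitium was compared with the proximal tubule to describe the compartment where fibrosis and immune cells gather. It held 656, 2013, 1067 and 770 squares in replicates 1, 5, 7 and 9. Of these, 11, 450, 407 and 10 were led by immunoglobulin genes. Those of a cluster led by MS4A1 and CCR7 numbered 8, 579, 201 and 3. The region was thus mostly fibroblast-led in replicates 1 and 9, and the folds below average over different mixes of interstitium. EPAS1 was higher in the interstitium by 1.04 ± 0.21 on the log2 scale (SE, n = 4; adjusted p = 4.66e-05) and the copper carrier CP, a HIF target, by 2.97 ± 0.33, each in 4 of 4 biopsies. CXCR4, a chemokine receptor, was higher by 2.85 ± 0.39 and SLC16A3 by 2.19 ± 0.34. VEGFA fell by 1.15 ± 0.19, P4HA2 by 1.93 ± 0.19 and AK4 by 1.96 ± 0.23, and HIF1A did not differ detectably (0.43 ± 0.26). SLC5A2 fell by 2.18 ± 0.29. With 32 um squares VEGFA stood at -1.96, AK4 at -3.40 and SLC5A2 at -3.46, and with regions from marker UMIs AK4 stood at -2.96 and SLC5A2 at -3.75. VHL, whose product marks HIF for degradation, was higher by 0.52 ± 0.16 (adjusted p = 0.00676), a call lost without replicate 1 (0.44), 5 (0.43) or 7 (0.42). HIF3A was higher by 1.31 ± 0.47, which did not pass without replicate 9 (0.75, adjusted p = 0.317). The matrix genes VCAN and POSTN were higher by 3.099 ± 0.41 and 2.93 ± 0.41, and the inflammatory genes CXCL1 and BIRC3 by 2.63 ± 0.56 and 2.52 ± 0.40. Glomerular markers (12 of 14 higher, median 1.53), endothelial markers (8 of 9, 1.28), vascular smooth muscle markers (8 of 8, 2.05) and intercalated cell markers (4 of 9, 0.90) moved with them.

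Of 11286 genes 2801 were higher and 2565 lower in the interstitium. Matrix and fibrosis genes had a median of 1.89 (16 higher, 0 lower of 17; adjusted p = 7.19e-09), fatty acid oxidation -1.28 (adjusted p = 1.63e-11), oxidative phosphorylation -0.78 (adjusted p = 3.05e-11), gluconeogenesis -2.09 (adjusted p = 2.81e-05) and glucose transport -1.97 (adjusted p = 0.00203). Inflammation genes had a median of 1.45 (9 higher, 0 lower of 13; adjusted p = 0.00205; adjusted p = 0.125 with an estimated correlation) and other tubular injury genes 0.82 (adjusted p = 0.0126; adjusted p = 0.214 with an estimated correlation). HIF targets had a median of -0.06 but a mean of 0.24 (test direction down, adjusted p = 0.777; 14 higher and 13 lower of 40, or 14 and 16 adjusted over the list alone). The median was 0.01 with clustering at resolution 0.5 and -0.24 without replicate 9. HIF targets outside glycolysis had a median of -0.23, a mean of 0.03 and a test direction of down (adjusted p = 0.201). Other tubular injury genes no longer passed in a fit on the 2 regions alone (0.81, adjusted p = 0.0808). Proximal tubule markers had a median of -2.29 (20 of 20 lower), and the lower metabolic lists were not tested apart from this general fall of proximal genes. Immunoglobulin genes, IGHG2 (5.54) and IGLC1 (5.27) first, were the largest rises, IGLC1 at 3.37 with regions from marker UMIs. They had taken part in clustering and may share reads with near copies, which was not tested, so single members are uncertain. RNF186 (-2.82), HPD (-2.78), FABP1 (-2.67) and PLG (-2.66) fell most, and FABP1 and HPD had taken part in clustering. Among genes that had not, 2024 were higher and 2397 lower of 9713.

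**Figure D3:**
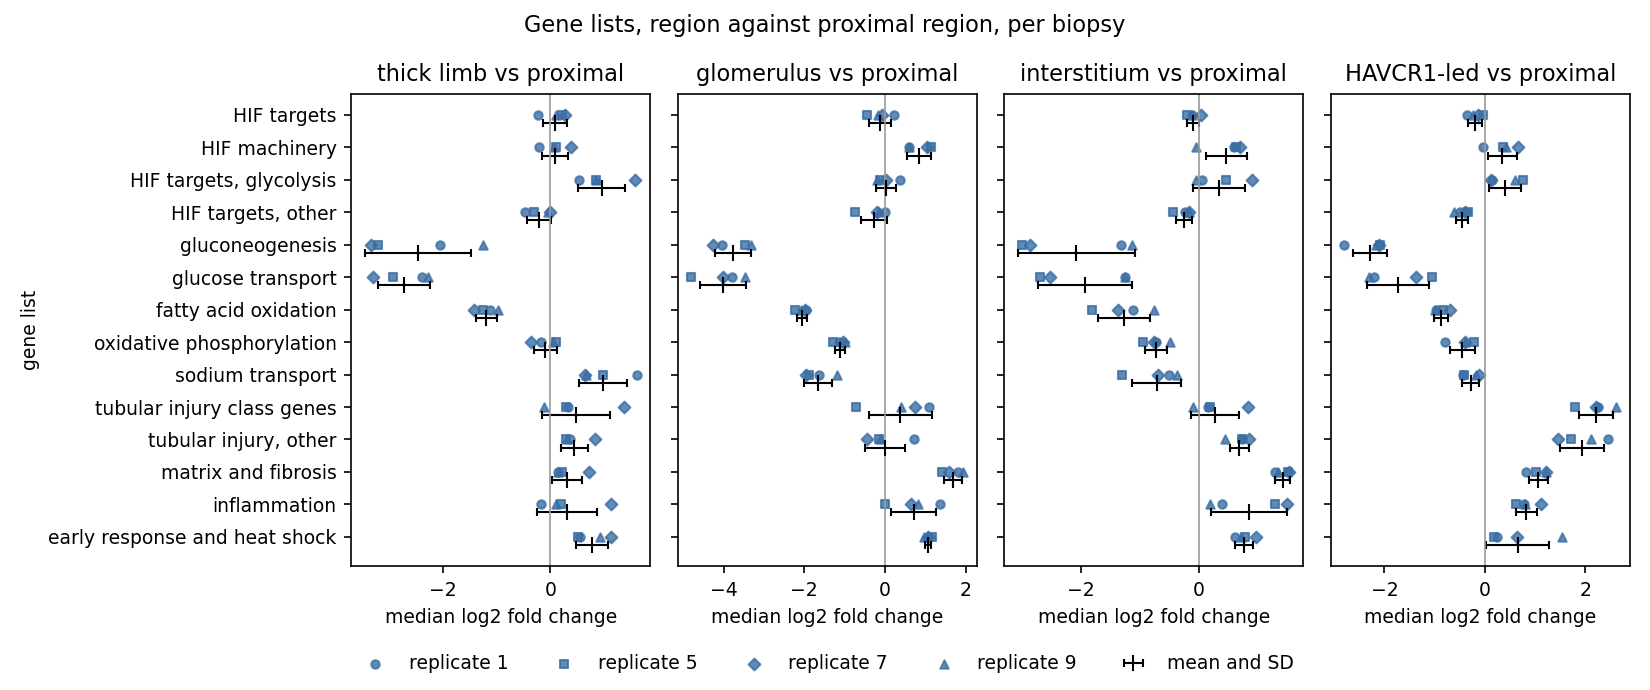
Median log2 fold change (horizontal axis) of 14 gene lists (vertical axis) in 4 regions against the proximal region; symbols are single biopsies, black marks their mean with SD (n = 4). Fatty acid oxidation genes lay below 0 in all 4 comparisons, and all HIF targets together lay near 0.

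HAVCR1-led squares were compared with the proximal region in a comparison added after the regions were seen. Injury and inflammation genes were higher: MMP7, a matrix protease, by 3.59 ± 0.41 on the log2 scale, the TWEAK receptor TNFRSF12A by 3.20 ± 0.29, the chemokine CXCL1 by 4.12 ± 0.53 and complement C3 by 3.18 ± 0.30 (SE, n = 4; adjusted p from 4.51e-08 to 1.72e-11), each in 4 of 4 biopsies. G6PC and PCK1, which make glucose, fell by 3.89 ± 0.30 and 3.49 ± 0.33, and SLC5A2 by 2.13 ± 0.31. HIF targets went both ways. VEGFA fell by 1.47 ± 0.21, P4HA2 by 2.28 ± 0.21 and the vascular peptide ADM by 1.92 ± 0.46, while the repressor BHLHE41 was higher by 2.55 ± 0.34, PFKP by 2.32 ± 0.30 and PLOD2, a collagen hydroxylase, by 1.34 ± 0.22. ENO2 was higher by 1.59 ± 0.45, a call lost without replicate 1 (1.31, adjusted p = 0.062). Of the HIF machinery none of 8 genes passed the test: HIF1A stood at 0.42 ± 0.30 (adjusted p = 0.335) and EPAS1 at -0.37 ± 0.21 (adjusted p = 0.212), although EPAS1 passed with 16 um squares (-0.75, adjusted p = 0.0063).

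**Figure D4:**
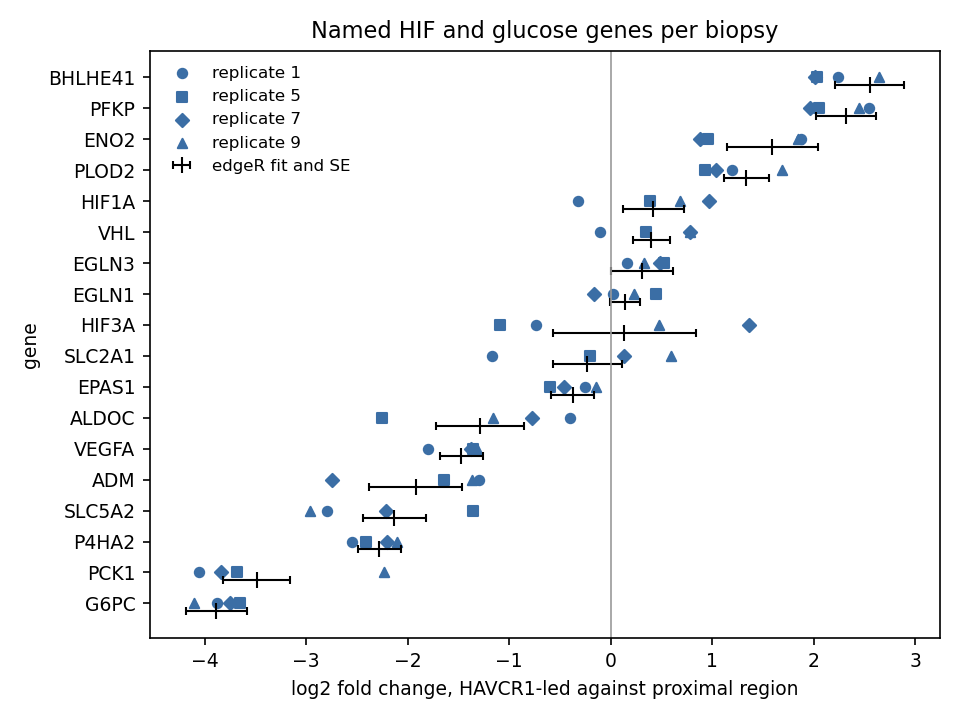
Log2 fold change in HAVCR1-led squares against the proximal region (horizontal axis) of 18 HIF and glucose genes (vertical axis); symbols are single biopsies, black marks the edgeR estimate with SE. VEGFA, ADM, P4HA2, PCK1 and G6PC lay below 0 and BHLHE41, PFKP and PLOD2 above 0 in all 4 biopsies.

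In HAVCR1-led squares 1401 genes were higher and 1533 lower of 11286. Tubular injury class genes had a median of 2.29 (11 higher, 0 lower of 11; adjusted p = 4.95e-14) and other tubular injury genes 2.13 (12 higher, 0 lower of 14; adjusted p = 4.05e-15). HAVCR1 itself belongs to the class and had named the region. A second feature of CCL2, another class gene, had taken part in clustering. The rise of the class list was thus in part set by how the region was chosen. HAVCR1 was higher there by 2.70 ± 0.34 on the log2 scale (SE, n = 4, edgeR adjusted p = 7.43e-08). Matrix and fibrosis genes had a median of 0.90 (adjusted p = 9.94e-08), inflammation 0.93 (adjusted p = 2.62e-06), while 3 of 9 fibroblast markers (median 0.26) and 3 of 17 immune markers (0.41) were higher. Gluconeogenesis genes had a median of -2.24 (adjusted p = 1.29e-07) and fatty acid oxidation -0.85 (adjusted p = 2.59e-08), beside proximal tubule markers at -2.36 (18 of 20 lower). HIF targets outside glycolysis had a median of -0.43 (2 higher, 13 lower of 29, or 4 and 14 adjusted over the list alone; adjusted p = 0.0094; adjusted p = 0.0578 with an estimated correlation) and glycolytic HIF targets 0.40 (3 higher, 1 lower of 11; adjusted p = 0.0247; adjusted p = 0.0578 with an estimated correlation). The glycolytic call was also lost with 16 um squares (0.29, adjusted p = 0.0834), at resolution 0.5 (0.38, adjusted p = 0.0635) and in a fit on the 2 regions alone (0.33, adjusted p = 0.0676). Calls lost with an estimated correlation were glucose transport (-1.64, adjusted p = 0.0053; adjusted p = 0.053 with an estimated correlation), oxidative phosphorylation (-0.39, adjusted p = 8.91e-06; adjusted p = 0.0935 with an estimated correlation) and early response and heat shock (0.71, adjusted p = 0.0247; adjusted p = 0.0935 with an estimated correlation), the last also without replicate 9 (0.37, adjusted p = 0.163), with no filter on low counts (0.41, adjusted p = 0.0572) and in a fit on the 2 regions alone (0.72, adjusted p = 0.0917). All HIF targets together had a median of -0.07 (adjusted p = 0.274; 5 higher and 14 lower of 40, or 7 and 15 adjusted over the list alone), which turned to 0.01 without replicate 1. CLDN1 (4.08), DLGAP1 (3.73), SBSPON (3.70) and SPON2 (3.57) were further large rises, and GSTA2 (-5.04), STRA6 (-4.97), GSTA1 (-4.64) and CALML3 (-4.64) fell most. GSTA1 and GSTA2 may share reads, which was not tested, and are uncertain singly. CLDN1, SBSPON and SPON2 had taken part in clustering, while DLGAP1 led the HAVCR1-led cluster and GSTA2, STRA6 and CALML3 a proximal cluster. Among genes that had not, 1138 were higher and 1391 lower of 9713.

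Proximal squares beside the interstitium were then compared with those away from it, to see whether squares of that region differed. HAVCR1-led squares formed a region of their own and were not among them. Of their neighbours 21.5% were interstitial, against 10.5% for proximal squares. The comparison thus does not cover all tubules beside the interstitium. Single transcripts were higher beside it: C1R, a complement protease, by 1.04 ± 0.18 on the log2 scale, TNXB by 0.97 ± 0.22, AEBP1 by 0.89 ± 0.18 and the protease inhibitor A2M by 0.71 ± 0.11 (SE, n = 4; adjusted p from 0.000774 to 0.0361), each in 4 of 4 biopsies. DEFB1, a defensin of distal tubules, fell by 0.92 ± 0.14. Without replicate 9 none of these passed (adjusted p from 0.134 to 0.686), and without replicate 1 C1R, TNXB and AEBP1 did not (adjusted p from 0.112 to 0.625). SLC5A2 (0.07 ± 0.13), HIF1A (0.17 ± 0.35), VEGFA (-0.06 ± 0.13) and EGLN1 (0.02 ± 0.15) did not differ detectably. EPAS1 was 0.39 ± 0.11 higher in 4 of 4 biopsies without passing the test (adjusted p = 0.248), and passed without the filter on low counts (0.44, adjusted p = 0.0473) and with squares of at least 200 UMIs (0.48, adjusted p = 0.0384). In all, 14 genes were higher and 7 lower of 8427. That count of 21 was 2 without replicate 9, 39 without replicate 7, 0 without the biopsy block and 0 in DESeq2 (81 at an unadjusted p under 0.05, against 514 in edgeR). It was 1463 with regions from marker UMIs, where no squares were set apart as HAVCR1-led, SLC5A2 stood at -1.04 and VEGFA at -0.54. Of 9 fibroblast markers 4 were higher (median 0.53), as were 2 of 9 immune markers (0.78), and 2 of 6 thick limb markers (-0.87) and 2 of 6 principal cell markers (-0.79) were lower. HAVCR1-led squares made up 0.933%, 4.61%, 4.11% and 0.933% of the neighbours of near squares in replicates 1, 5, 7 and 9, and 1.045%, 1.598%, 0.414% and 0.335% of those of far squares. In replicate 5 near squares had a median of 470 UMIs and far squares 244. Matrix and fibrosis genes (median 0.27; 0 of 11 called), inflammation genes (0.20; 1 of 8) and gluconeogenesis genes (-0.17) each had adjusted p = 0.0488, and adjusted p = 0.37 with an estimated correlation, and each call was lost without at least 1 biopsy (adjusted p = 0.141 for each without replicate 9). Fatty acid oxidation passed with 16 um squares (-0.18, adjusted p = 0.00232), at resolution 0.5 (-0.09, adjusted p = 0.0366) and with regions from marker UMIs (-0.48, adjusted p = 6.7e-08), and oxidative phosphorylation likewise (-0.12, -0.10 and -0.30; adjusted p = 0.0215, 0.0413 and 2.3e-07). Sodium transport passed with 16 um squares (-0.20, adjusted p = 0.00882) and at resolution 0.5 (-0.22, adjusted p = 0.0125), and other tubular injury genes with 32 um squares (0.33, adjusted p = 0.00513), at resolution 0.5 (0.19, adjusted p = 0.0366) and with regions from marker UMIs (1.12, adjusted p = 1.81e-08). Regions from marker UMIs also gave calls for glucose transport (-0.94, adjusted p = 0.0004), HIF targets outside glycolysis (-0.29, adjusted p = 0.0121) and early response and heat shock (0.51, adjusted p = 0.0352). Tubular injury class genes had a median of -0.06, a mean of 0.07 and a test direction of up (adjusted p = 0.3). Their median changed sign and the list passed at resolution 0.5 (0.12, adjusted p = 0.0366) and with regions from marker UMIs (1.42, adjusted p = 8.09e-10). HIF targets had a median of -0.07 (adjusted p = 0.123), with 0 of 27 passing over all genes and 0 adjusted over the list alone. A2M, AEBP1, DEFB1, EHBP1L1 and TNXB had taken part in clustering, and among genes that had not, 1 was higher and 0 lower of 7459.

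In the thick limb, squares beside the interstitium had more VIM, an intermediate filament protein of stromal and injured cells, by 0.97 ± 0.20, SPARC, a matrix protein, by 0.89 ± 0.20, RNASE1 by 1.004 ± 0.22 and LRP1 by 1.36 ± 0.35 (log2, SE, n = 4; adjusted p from 0.00318 to 0.0393). ATP6V0A4, a proton pump subunit of intercalated cells, fell by 0.97 ± 0.24 and WDR13 by 1.07 ± 0.28. In all, 9 genes were higher and 5 lower of 1915 tested. Some classes were small, with 30 far squares in replicate 7 and 49 near squares in replicate 9. In replicate 7 near squares had a median of 1371 UMIs and far squares 828. That count of 14 was between 5 and 9 with any 1 biopsy left out, 0 without the biopsy block and 1 in DESeq2. The genes called changed too. Of the 14, only 2, 5, 4 and 2 were called again without replicates 1, 5, 7 and 9. With 16 um and 32 um squares 3 and 3 were called again, and at resolution 0.5 13 were. Immune markers had a median of 1.25 (2 of 3 higher) and principal cell markers -1.26 (2 of 2 lower). Vascular smooth muscle markers had a median of 1.04 (1 of 4 higher) and fibroblast markers 0.62 (0 of 7 called). No list passed, with inflammation (0.67) and sodium transport (-0.22) nearest at adjusted p = 0.0816. Sodium transport passed without replicate 9 (-0.38, adjusted p = 0.0352), at resolution 0.5 (-0.27, adjusted p = 0.0482) and with 3 neighbours (-0.76, adjusted p = 0.00612), inflammation without replicate 7 (0.64, adjusted p = 0.0272) and at resolution 0.5 (0.55, adjusted p = 0.0482), and matrix and fibrosis without replicate 1 (0.38, adjusted p = 0.0233) and with 3 neighbours (0.64, adjusted p = 0.0407). Gluconeogenesis passed with 16 um squares (-0.76, adjusted p = 0.00424), fatty acid oxidation with 32 um squares (-0.32, adjusted p = 0.0102), and other tubular injury genes with 32 um squares (0.22, adjusted p = 0.0102), regions from marker UMIs (0.37, adjusted p = 0.0377) and 3 neighbours (0.27, adjusted p = 0.00612). EPAS1 was 0.54 ± 0.17 higher without passing (adjusted p = 0.182), but passed with 16 um squares (0.90, adjusted p = 0.0239). HIF targets had a median of 0.08 (adjusted p = 0.513), which turned to -0.03 without replicate 1 or 5. On simulated counts a shift of 0.5 in this list was not detected by camera in this comparison (median 0.25), so a shift of that size could have been missed. A2M, ATP6V0A4, LRP1 and RNASE1 had taken part in clustering, and among genes that had not, 3 were higher and 1 lower of 1653. The effect of lying beside the interstitium was also compared between thick limb and proximal squares by an interaction term in edgeR, which found 0 genes of 7980, with 377 at an unadjusted p under 0.05. DESeq2 was not run on this term.

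Proximal squares with a UMI of an injury class gene, 4.79%, 6.81%, 5.06% and 4.93% of proximal squares in replicates 1, 5, 7 and 9, were compared with those without. HAVCR1-led squares were not among them. VIM was higher by 0.76 ± 0.13 on the log2 scale (SE, n = 4; adjusted p = 0.000428; higher in 4 of 4 biopsies) and was the 1 gene that passed of 8025. It did not pass in DESeq2 (adjusted p = 0.0585) or without replicate 9 (0.59, adjusted p = 0.922), and stood at -0.09 when the class needed 2 UMIs. SLC5A2 (0.02 ± 0.14), EPAS1 (0.02 ± 0.14), HIF1A (0.40 ± 0.50) and VEGFA (-0.04 ± 0.19) did not differ detectably. Other tubular injury genes had a median of 0.32 (adjusted p = 0.00144; adjusted p = 0.495 with an estimated correlation) and inflammation genes 0.38 (adjusted p = 0.0399; adjusted p = 0.724 with an estimated correlation). The first was lost without replicate 9 (0.27, adjusted p = 0.187), and the second without any 1 of the 4 biopsies (adjusted p from 0.0662 to 0.24). The first was also lost with 32 um squares (0.26, adjusted p = 0.302), and the second with no filter on low counts, 16 um or 32 um squares, at least 200 UMIs or resolution 0.5 (adjusted p = 0.204, 0.544, 0.741, 0.0727 and 0.143). When the class needed 2 UMIs both changed sign without passing (-0.89 and -1.66, each adjusted p = 0.407). HIF targets had a median of -0.07 (adjusted p = 0.776), 0.00 with 32 um squares and -2.11 when the class needed 2 UMIs (adjusted p = 0.715). The count of 1 gene was 518 with regions from marker UMIs and 301 when the class needed 2 UMIs, where SLC5A2 stood at -0.54 and -2.35. Regions from marker UMIs also gave calls for gluconeogenesis (-0.49, adjusted p = 0.0141) and glucose transport (-0.44, adjusted p = 0.0445). They did so too for fatty acid oxidation (-0.24, adjusted p = 0.0014) and matrix and fibrosis genes (0.35, adjusted p = 0.0366). The class with at least 2 UMIs held only 2, 11, 4 and 6 squares in replicates 1, 5, 7 and 9.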

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

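The tests of mixing and of matched random lists below were chosen only after the results they weigh were seen. A sample was marked when it stood far from the other 3 by Dixon's test, which marked 16 of 341 groups. Chance flags about 1 in 20 groups, or 17.1 here, so the number gives no sign of more than chance.

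In the thick limb against the proximal region, SLC9A3R1 stood at -1.97 in replicate 9 (others -2.67 to -2.56), other tubular injury genes at a median of 0.82 in replicate 7 (0.29 to 0.37) and matrix and fibrosis genes at 0.72 in replicate 7 (0.14 to 0.22). MMP7 in the glomerular region stood at 2.28 in replicate 1 (0.64 to 0.83). In the interstitium, replicate 9 stood apart for IGLC3 (0.94, others 4.70 to 4.96), HIF3A (1.67, others 0.64 to 0.81) and HIF machinery (-0.04, others 0.60 to 0.70). Replicate 1 did for CCL2 (0.86, others 1.76 to 1.80) and SLC2A1 (-0.15, others 0.78 to 0.90), replicate 7 for PROM1 (2.64, others 0.38 to 0.66) and replicate 5 for ENO1 (-0.09, others -0.77 to -0.69). In HAVCR1-led squares VEGFA stood at -1.80 in replicate 1 (-1.38 to -1.31) and gluconeogenesis at -2.80 in replicate 1 (-2.17 to -2.08). Beside the interstitium, A2M in proximal squares stood at 0.87 in replicate 9 (0.60 to 0.64) and EPAS1 in the thick limb at 0.94 in replicate 1 (0.40 to 0.48). Proximal squares with an injury UMI made up 6.81% in replicate 5 (4.79% to 5.06%).

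Signals outside the squares compared were listed too. A cluster led by haemoglobin genes held 47, 8, 265 and 79 squares in replicates 1, 5, 7 and 9. Whether copies of these genes share reads was not tested. Named regions left out 11.7%, 14.03%, 13.79% and 16.95% of the deposited UMIs.

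The first pattern weighed was the lower level of HIF targets outside glycolysis in HAVCR1-led squares. Mixing with interstitial RNA, at the share set by fibroblast and immune markers, predicted a shift of 0.004 and left a residual of -0.21 ± 0.164 (SD, n = 4). A second form, relative to the median gene, predicted -0.019 and left -0.486 ± 0.148. Both residuals lay outside 1 SD of 0, so the modelled interstitial share did not account for the fall by that rule. A spread over 4 biopsies is a loose limit, and RNA of other regions was not modelled, so mixing is not excluded. Among 10000 random lists matched on proximal specificity and level, the list lay at percentile 0.05 (random 95% from -0.264 to 0.199). It was thus lower than most lists of similar genes. The lists were not matched on correlation between genes, so a general loss of proximal transcripts is not excluded. The list's own test had adjusted p = 0.0578 with an estimated correlation. No biological explanation was tested.

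The second pattern was the higher level of glycolytic HIF targets in the same squares. The matched lists put it at percentile 56.91, so what similar genes did there could account for it. For mixing, 2 forms differed. On plain proportions the list stood at 0.765 with a residual of 0.50 ± 0.384, outside 1 SD of 0. Relative to the median gene it stood at 0.453 with a residual of 0.316 ± 0.495, inside 1 SD, so mixing could not be judged. The rule that all forms must give the same verdict was set after these results.

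The third pattern was the difference beside the interstitium in proximal squares. After a mixing share of 9.12%, 7 called genes that are no markers, chosen on the same data, kept a residual of 0.16 ± 0.150 (observed 0.907, expected 0.778). The test was run in 4 forms, the last 3 written after the first was seen: the residual was 0.153 ± 0.139 relative to the median gene, -0.222 ± 0.120 for held-out genes ranked by fold, which moved little themselves (0.128), and 0.015 ± 0.090 for held-out genes ranked by z. The verdict changed with the form, so it was left open whether RNA of neighbouring interstitium accounts for the observed rise. For the lower distal transcripts, far squares had 3.92 ± 4.90 percentage points more neighbours in thick limb, distal, principal or intercalated regions, higher in 3 of 4 biopsies, so this could not be judged.

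Whether chance could be excluded was asked of each count of changed genes by dividing the 8 sums into other sets of 4 and 4. For the thick limb 1 of 35 splits changed as many genes, the real one (3915; highest other 636, or 16 among the 8 splits that part every pair). The same 1 of 35 held for the glomerulus (5791; 2007 and 1792), the interstitium (5366; 1583 and 954) and HAVCR1-led squares (2934; 472 and 65), and 1 of 32 fitted splits for the thick limb beside the interstitium (14; 3 and 1). The regions were drawn by clustering the same counts, which favours the real split, so for the 4 region comparisons these counts cannot exclude chance. The sums are paired by biopsy, and the 8 splits that part every pair are too few for a share under 0.05. For proximal squares beside the interstitium 2 of 32 splits changed as many (21; highest other 21) and for injury UMIs 12 of 32 (1; highest other 1), so chance was not excluded.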

How the results depend on the processing

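Every alternative for HAVCR1-led squares was chosen after seeing the data, and regions from marker UMIs gave no such region. The counts of changed genes in the 4 region comparisons stayed within 1.5 times under all alternatives (14, 14, 14 and 13), and the proximal share of 38.1% ranged from 35.6% to 41.1% over the alternatives planned for it, but was 59.9% with marker regions. Of 3200 gene values 3011 kept their call, 170 were weaker, 12 stronger and 7 reversed; of 1208 list values the numbers were 1108, 59, 35 and 6. Of those that kept their call, 62 gene and 54 list values changed sign without passing the test. The cause was not tested for any change below. For single genes power was lowest in the injury comparison, which recovered 32% of 2-fold changes on simulated counts, against 48% to 69% in the others. A simulated shift of 0.5 in the HIF target list was missed only in the thick limb squares near and far (median 0.25). The simulation gave both classes otherwise equal means, unlike the real regions, so it does not show that such a shift would be seen there. In the real thick limb comparison, injury class genes at a median of 0.62 did not pass (camera adjusted p = 0.157). Other tubular injury genes at 0.59 did (camera adjusted p = 0.00476).

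Without the biopsy block, which pairs the sums of a biopsy, edgeR called 0 genes in proximal squares beside the interstitium (239 at an unadjusted p under 0.05), 0 in the thick limb (125) and 0 for injury UMIs (272), HIF targets beside the interstitium in the thick limb stood at -0.0751, and 25 gene and 3 list calls were lost.

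The median of HIF targets changed sign in the thick limb without replicate 7 (leave-one-out -0.0354 to 0.136) and with no filter (-0.13), in the interstitium at resolution 0.5 (0.0128), in HAVCR1-led squares with 1 biopsy left out (-0.143 to 0.007) and for injury UMIs with 32 um squares (0.0037). Beside the interstitium in the thick limb it did with 1 biopsy left out (-0.0332 to 0.1105), 16 um (-0.0474) and 32 um squares (-0.19), marker regions (-0.25) and 3 neighbours (-0.11).

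The 21 genes beside the interstitium in proximal squares became 2 to 39 with 1 biopsy left out, 38 with no filter, 57 with 16 um squares, 40 at resolution 0.5, 1463 with marker regions and 0 in DESeq2 (81 at an unadjusted p under 0.05). The 14 in the thick limb became 5 to 9, 24 with 16 um squares, 63 with 32 um squares, 23 at resolution 0.5, 22 with 3 neighbours and 1 in DESeq2. The 1 gene for injury UMIs became 0 to 1 with 1 biopsy left out, 2 with RLE factors, 13 with no filter, 0 with 16 um squares (448 at an unadjusted p under 0.05), 0 with 32 um squares (328), 518 with marker regions, 301 with at least 2 UMIs and 0 in DESeq2 (102).

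Reversed genes were TNC in the thick limb (-0.0659, marker regions), SLC5A2 in proximal squares beside the interstitium (-1.04, marker regions), A2M (-0.0895, 32 um squares) and WDR13 (0.12, marker regions) in the thick limb beside it, and for injury UMIs SLC5A2 (-0.54, marker regions; -2.35, at least 2 UMIs) and VIM (-0.0948, at least 2 UMIs). Reversed lists were other tubular injury genes in the thick limb (-0.0203, 16 um squares; -0.0595, marker regions), injury class genes beside the interstitium (0.12, resolution 0.5; 1.42, marker regions), and for injury UMIs other tubular injury genes (-0.89) and inflammation (-1.66), both with at least 2 UMIs, a class of 23 squares in all.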

Other observations

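The neighbour test below was chosen only after the result was seen. HAVCR1-led squares lay beside the interstitium more often than proximal squares: 21.5% ± 7.87 of their neighbours were interstitial against 10.5% ± 2.06 (SD, n = 4), higher in 4 of 4 biopsies. The exact sign-flip p was 0.125, the smallest that 4 biopsies allow.

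Squares led by immunoglobulin genes numbered 11, 450, 407 and 10 in replicates 1, 5, 7 and 9. Squares of the immune cluster led by MS4A1, CCR7, BLK and IL7R numbered 8, 579, 201 and 3. Replicates 5 and 7 thus differed from 1 and 9 in these squares as in their proximal clusters. The difference between these biopsies was not tested.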
